A study of Mus musculus with 2 samples.

How the data were processed

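Plate files and a table of ratios were used, all from RAW264.7 cells, a mouse macrophage cell line. Per the labels' protocols, a probe was transfected into the cells for 24 hours, the captured RNA was purified on streptavidin beads and extracted, and miRNAs were measured by real-time PCR with SYBR green on Exiqon multiplex miRNA arrays. The labels give 1 pull-down made with a control probe and 1 made with a probe for Stat3 mRNA. The probe sequences and the Stat3 segment they cover are not given in the sources used here.

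Per the file headers, each plate file is an export of the SDS 2.3 software and holds a raw threshold cycle (Ct) for each of 384 wells, with a manual threshold of 0.15. For 1 assay, a lower Ct means more template, and 1 cycle stands for a factor of 2 if amplification is complete. The deposited plate values are in cycles with no normalization, although the labels describe the value of each sample as a relative level, and they carry no miRNA names. The authors' deposited table gives 1 value for each of 384 named assays, and its header calls the value a log fold change of Stat3 probe over control probe. The values of that table behaved as linear ratios: all 384, with both sets sorted, equalled 2 to the power of (0.7 + control Ct − Stat3 Ct) of the wells, within 0.0005, when every Ct above 35 and every undetermined well was set to 35. Of the 384 rows, 238 shared the value 1.625, which is the offset of 0.7 cycles alone, and 238 wells were at or above a Ct of 35 on both plates. The ceiling and the offset were recovered here from the values and are stated in no header or label.

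This identity was used to attach assay names to wells. Of the 146 rows with another value, 142 matched exactly 1 well and 4 matched a pair of wells. Under 999 other offsets at most 9 of the 146 rows found a well, and under ceilings other than 35 at most 108 did. One ambiguous pair was miR-451 and the UniSp6 spike-in, whose ratios were equal to 3 decimals. The spike-in was assumed to be the well with the lowest Ct on either plate, and the level of miR-451 rests on this assumption. The Ct difference of 0.70 cycles, which equals the offset, holds for both wells of the pair and does not tell them apart. For the other pair, miR-326 and miR-294, no Ct was assigned. The 238 rows at the ceiling in both pull-downs have no well here.

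An assay was called measured in a pull-down if its Ct was below 35. Ratios are Stat3 probe over control probe on the scale of the authors' deposited fold values and were recomputed from the plates, which returns the deposited ratio for the assays measured in both. Where only 1 pull-down was below 35, the ratio with the other at 35 is a bound and is written as such. The design had been written for relative levels rather than Ct values, and the log2 ratio is the same quantity in either form. No pseudocount was used. With 1 pull-down per group there is no test between the probes, and no p-value, SD or standard error between samples is given. The precision is not known from replicates. The spread of the 3 wells of the UniSp3 calibrator, a fixed template in every plate, is given as the only error measured on these plates. It covers the PCR and the well, not the pull-down. Level stands for Ct in what follows, and since assays can differ in efficiency and background, their order by level is one of Ct and not of abundance.

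Rules fixed before the data were examined named the 12 highest and 12 lowest ratios among assays whose mean level was at or above the median, the 5 highest levels seen with only 1 probe, the 5 highest levels with each probe, and the members of fixed miRNA lists. A list member was matched to the assay under its older mouse name where several assays carried its number. This is a looser reading than the rule fixed beforehand, which matched a name without an arm only where 1 assay carried that number. Outside the list of the imprinted Dlk1-Dio3 cluster, a rat-named assay was taken only if no mouse-named one was on the plate. That list also holds rat-named assays of miR-136, miR-337, miR-377, miR-381 and miR-493 beside mouse-named ones. For lists with at least 3 members measured in both pull-downs, the median log2 ratio was placed among 10000 random lists of the same size drawn from 5 bins of mean level. Such a percentile describes these pull-downs and is not a p-value. In a simulation of this comparison over 384 wells, 123 of 127 informative rows were matched to their own well alone and 0 to a wrong one. In it, 100% of wells changed 4-fold passed a 2-fold threshold, and 0% of unchanged wells did. The noise simulated for single wells was far below the calibrator SD of 0.97 cycles. Those shares therefore follow from the setting and do not show how reliable a 2-fold difference is on these plates. Of 100 simulated lists of 6 raised 4-fold, 80 exceeded a percentile of 97.5, and of 100 random lists 3 fell outside 2.5 to 97.5, so some lists with a real shift of that size are missed. All simulated lists had 6 members, so the share found does not describe lists with fewer measured members, some of which had only 3. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

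The alternatives tried were other scales, level filters, fold thresholds and Ct limits, the authors' table as it stands, and subsets of wells. The search for seed matches in Stat3 mRNA was not run, since no transcript or mature miRNA sequences were used here. The table of mouse genes (assembly GRCm38.p6) served only to find which miRNA genes are neighbours, and no coordinates are given because the data name no genome build.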

Results

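The miRNAs that came down with a Stat3 mRNA probe were compared with those that came down with a control probe in RAW264.7 mouse macrophages, to find miRNAs associated with Stat3 mRNA. Stat3 is a transcription factor that acts downstream of cytokines such as IL-6 and IL-10. Each probe is represented by 1 pull-down and 1 plate of 384 wells. Of the miRNA assays on the plate, 35 carry rat names, and 8 further assays are controls or a blank. With the control probe 209 wells gave a Ct and 175 were undetermined, and 121 lay below the limit of 35 cycles. With the Stat3 probe 225 wells gave a Ct and 159 were undetermined, and 132 lay below 35. Of the miRNA assays, 100 were measured in both pull-downs, 25 only with the Stat3 probe, 14 only with the control probe and 237 in neither.

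Most miRNAs measured in both pull-downs had a higher level with the Stat3 probe. The median ratio was 4.22-fold, with quartiles of 1.94-fold and 6.80-fold. Of the 100 assays, 73 were at least 2-fold higher, 25 lay within 2-fold and 2 were at least 2-fold lower. At a 4-fold limit 53 were higher and 1 was lower. Relative to the median of all miRNAs, 16 were at least 2-fold higher and 30 at least 2-fold lower. Ct values of the pull-downs were correlated across these assays (Pearson r = 0.80, Spearman rho = 0.80), and in the 50 assays of higher level r was 0.43. Those 50 are chosen by the mean of the same Ct values, which narrows the range of Ct and by itself lowers r. The ratios have no replicate check. Scaled to the 4 measured reference miRNAs fixed beforehand (miR-103, miR-191, miR-423-3p and miR-16), 11 assays were at least 2-fold higher and 42 at least 2-fold lower, and the median log2 ratio changed from 2.08 to -0.49. Without miR-423-3p among the references, a choice made after its ratio was seen, these values were 32, 14 and 0.52.

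**Figure D1:**
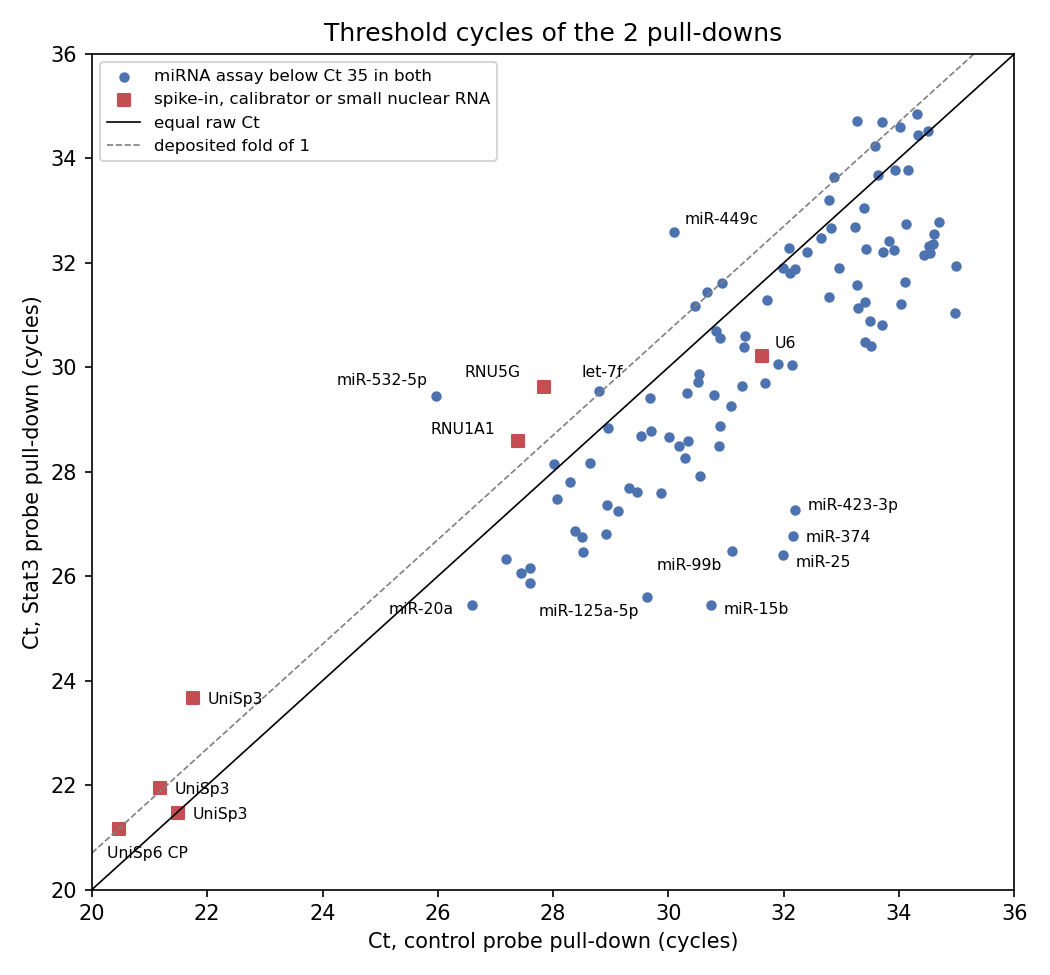
Ct of each assay below 35 cycles in both pull-downs, control probe on the x axis and Stat3 probe on the y axis, in cycles. Points are the 100 miRNA assays and squares the spike-in, calibrator and small nuclear RNA wells, and most miRNAs lie below both lines, with miR-25, miR-374 and miR-15b farthest below and miR-532-5p farthest above.

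Among the assays of higher level, 6 miRNAs stood well above the rest. Level is the mean of both Ct values, with a median of 31.02, so a low Ct with the Stat3 probe helps an assay enter this group. The control Ct alone was above 31.02 for miR-25, miR-374 (32.16), miR-423-3p (32.20) and miR-99b (31.10). It was below 31.02 for miR-15b (30.74) and miR-125a-5p (29.64). miR-25, a member of the miR-106b~25 cluster, had a Ct of 31.98 with the control probe and 26.41 with the Stat3 probe, a ratio of 77.2-fold. miR-374 was 68.0-fold higher and miR-15b, of the miR-15/16 family, 64.0-fold higher. miR-423-3p was 49.5-fold higher. miR-99b and miR-125a-5p, which are processed from one cluster with let-7e, were 40.1-fold and 26.6-fold higher, and let-7e itself 8.46-fold. The other 5 of the 12 highest were miR-27b at 10.1-fold, miR-320 at 7.90-fold, let-7b at 7.03-fold, miR-125b-5p at 6.74-fold and miR-27a at 6.63-fold. The first 6 also lay above the median of all miRNAs, by 18.3-fold for miR-25 and 6.31-fold for miR-125a-5p. That median pools all plate rows. All of the 12 but miR-423-3p lie in rows A, C, E and so on, where the median was 5.01-fold. In the other rows, which hold miR-423-3p, it was 1.80-fold. The order of the 12 is not corrected for this difference.

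miR-532-5p had the lowest Ct of the miRNA assays with the control probe, 25.98, and had a ratio of 0.146 with the Stat3 probe, at a Ct of 29.46. The other assay at least 2-fold lower, named after its value was seen, was miR-449c, with Ct values of 30.10 and 32.59 and a ratio of 0.288. Next among the assays of higher level came let-7f at 0.964-fold, miR-451, an erythroid miRNA, at 1.0-fold, and miR-103 at 1.47-fold. miR-155, which is induced by inflammatory stimuli in macrophages, was at 1.76-fold, miR-18a at 1.78-fold and miR-15a at 1.97-fold. miR-484, miR-222, the rat-named miR-146b assay, miR-142-3p and miR-151-5p lay between 2.05-fold and 2.58-fold. Of these 12, only miR-532-5p was lower by more than 2-fold. Among them, miR-103, miR-155, the rat-named miR-146b assay and miR-151-5p lie in plate rows B, D, F and so on. Ratios were lower in those rows, with a median of 1.80-fold. Against it miR-103 and miR-155 were lower, miR-155 only slightly, and the other named assays of those rows were higher. After miR-532-5p, the lowest Ct values with the control probe were those of miR-20a, miR-21, miR-16 and miR-24, at 26.59 to 27.60. With the Stat3 probe they were those of miR-20a, miR-15b, miR-125a-5p, miR-24 and miR-16, at 25.44 to 26.07.

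Of the 25 miRNA assays measured only with the Stat3 probe, 23 were at least 2-fold higher as a bound. The lowest Ct values were those of miR-151-3p at 28.84, miR-184 at 29.28, miR-181a at 30.53, miR-504 at 30.76 and miR-30d at 31.77. With the control probe set at 35 cycles these were at least 116-fold, 85.3-fold, 36.1-fold, 30.7-fold and 15.2-fold higher. All 5 gave a Ct between 35.13 and 37.79 with the control probe, and from those values the ratios were 260-fold, 220.2-fold, 39.5-fold, 212-fold and 50.5-fold. The 14 assays measured only with the control probe were led by miR-124, a neural miRNA, at a Ct of 32.76 and a ratio of at most 0.344. It was followed by miR-219-5p at most 0.544, miR-490-3p at most 0.755, the rat-named miR-200b assay at most 0.779 and miR-187 at most 0.79. The authors' deposited table lists a ratio above 1 for 8 of the 14, although they were below 35 cycles only with the control probe, since the offset of 0.7 cycles is part of the ratio. Detection in 1 pull-down depended on the limit of 35 cycles: with any determined Ct counted, 3 of the assays tied to a well were seen only with the Stat3 probe and 10 only with the control probe, while over all 384 wells, named or not, the numbers were 63 and 47.

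The let-7 family, which restrains growth and cell cycle genes, had the highest list median, 5.87-fold over 8 members measured in both pull-downs, with 6 at least 2-fold higher. let-7e, let-7b, let-7d, let-7c, let-7a and let-7g lay between 8.46-fold and 5.03-fold, let-7i was at 1.83-fold and let-7f at 0.964-fold. The well of let-7i carried an instrument warning in either pull-down or both. miR-98 was measured only with the Stat3 probe and was at least 4.27-fold higher. Members of this family differ by few bases, and the assays can share signal. The list stood at percentile 84.4 of random lists matched on level. All 5 members of the miR-23/27/24 clusters were at least 2-fold higher, from 4.66-fold for miR-23a to 10.1-fold for miR-27b, at percentile 74.0. In the miR-30 family 3 members were measured in both pull-downs, miR-30a at 7.61-fold, miR-30b at 5.76-fold and miR-30c at 2.92-fold, while miR-30d and miR-30e were measured only with the Stat3 probe, and the list stood at percentile 71.6.

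The miR-17 seed family, products of growth-promoting clusters, had a median of 3.19-fold over 4 measured members. miR-93 was at 5.84-fold, miR-20a at 3.60-fold, miR-17 at 2.83-fold and miR-106a at 2.04-fold, while miR-20b and miR-106b were not below 35 cycles in either pull-down. The list stood at percentile 25.8. The wider set of guide strands from the miR-17 cluster and its paralogous clusters had 12 of its 13 members on the plate, without miR-92a. It had 7 measured members, 6 of them at least 2-fold higher, a median of 3.07-fold and percentile 29.7, and held miR-25 together with miR-18a. In the miR-15/16 family 4 of 6 members were at least 2-fold higher, with a median of 2.70-fold and percentile 17.5. Its members ranged from miR-15b at 64.0-fold through miR-16 at 4.22-fold to miR-497 at 1.12-fold. The miR-29 family had a median of 2.13-fold over 3 members, from miR-29a at 3.67-fold to miR-29b at 1.09-fold, and percentile 45.4. miR-181a and miR-181b were measured only with the Stat3 probe, as were miR-148b, at least 6.49-fold higher, and miR-152, at least 5.72-fold higher. Of the miR-130 and miR-301 family, miR-130b was at 2.04-fold and miR-301b at 1.81-fold.

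**Figure D2:**
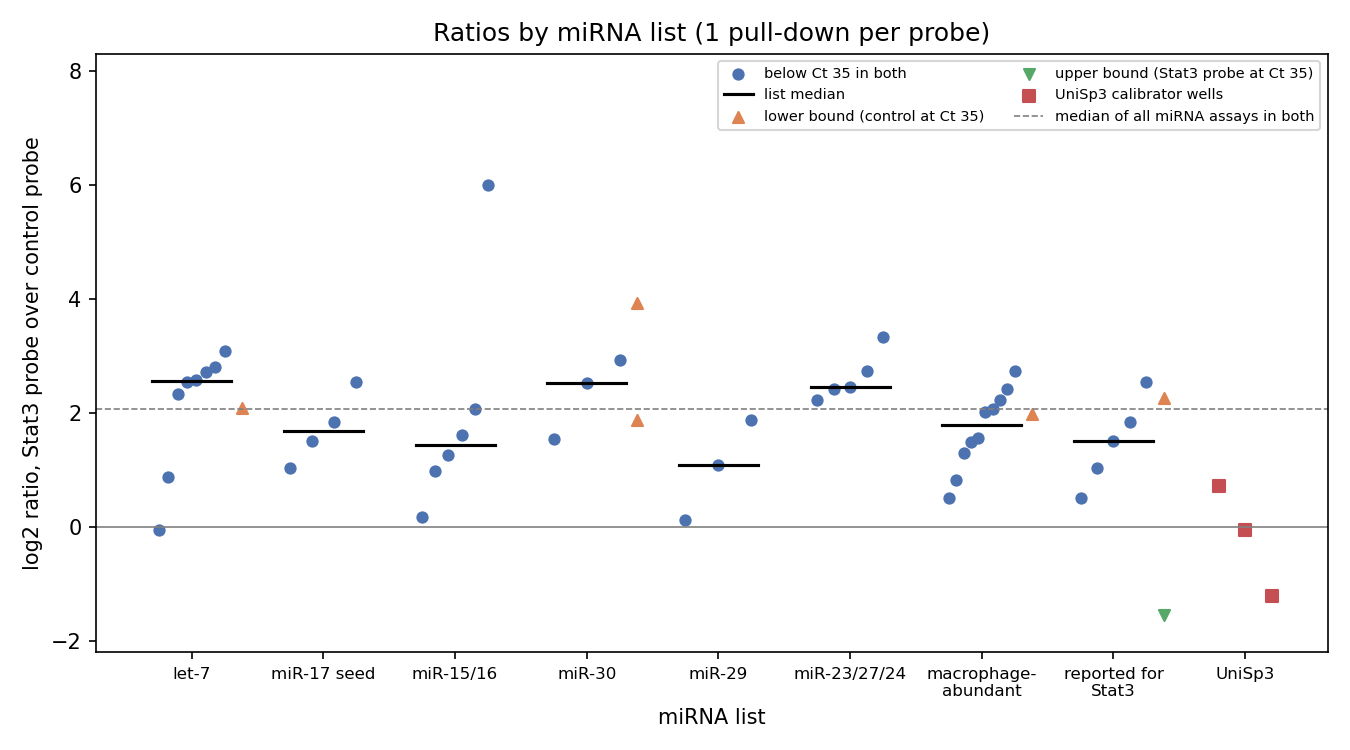
Log2 ratio of Stat3 probe over control probe (y axis) for the members of 8 miRNA lists and the UniSp3 calibrator wells (x axis). Dots are assays measured in both pull-downs, short lines list medians and triangles bounds where 1 pull-down was at 35 cycles. The dashed line is the median of all 100 miRNA assays, 2.08, above which lie the medians of the let-7, miR-30 and miR-23/27/24 lists. On the scale of the 4 reference miRNAs these 3 fall below 0, and without miR-423-3p among the references they lie above it, in both cases with no correction for plate rows.

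Of the 12 miRNAs listed as abundant in macrophages, 10 were measured in both pull-downs and 8 were at least 2-fold higher. Their median was 3.47-fold, at percentile 8.92. miR-27a was at 6.63-fold, miR-24 at 5.36-fold, miR-191 at 4.06-fold, miR-21 at 2.96-fold and miR-142-3p at 2.44-fold. miR-223, a myeloid miRNA, was at 1.42-fold, miR-22 was at least 3.93-fold higher, and miR-142-5p was not below 35 cycles in either. The list of inflammation-responsive miRNAs had a median of 2.81-fold over 7 measured members, at percentile 9.91. It ran from miR-9 at 7.22-fold and miR-125b-5p at 6.74-fold through miR-146a, a feedback inhibitor of Toll-like receptor signalling, at 2.81-fold, to miR-155 and miR-223, while miR-187 was measured only with the control probe. miR-132 and miR-212-3p were measured only with the Stat3 probe, at least 7.23-fold and 3.75-fold higher, and miR-147 in neither. The wells of miR-132 and miR-212-3p carried an instrument warning in either pull-down or both.

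Of 10 miRNAs listed beforehand from general knowledge as acting on Stat3 mRNA, 5 were measured in both pull-downs and 4 of these were at least 2-fold higher. let-7a was at 5.80-fold, miR-20a at 3.60-fold, miR-17 at 2.83-fold, miR-106a at 2.04-fold and miR-223 at 1.42-fold. miR-874 was at least 4.82-fold higher and miR-124 had a ratio of at most 0.344, while miR-20b, miR-106b and miR-337-3p were not below 35 cycles in either. The median was 2.83-fold, at percentile 29.3. Relative to the median log2 ratio of all 100 miRNAs, the medians were -0.58 for this list, -0.28 for the macrophage-abundant, -0.59 for the inflammation-responsive, -0.40 for the miR-17 seed, -0.46 for the miR-17 cluster, -0.64 for the miR-15/16 and -0.98 for the miR-29 list. Those of the let-7, miR-30 and miR-23/27/24 lists were 0.48, 0.45 and 0.38, but all their measured members lie in plate rows A, C, E and so on, where ratios were higher, and against the median of those rows they were 0.23, 0.20 and 0.13. On the scale of the 4 reference miRNAs, whose mean log2 ratio was 2.57, the median of each of these 10 lists lay below 0, by as little as -0.017 for let-7. That direction rests on miR-423-3p: without it the reference mean was 1.55 and 6 of the 10 medians lay above 0, those of let-7 (1.002), miR-30 (0.98) and miR-23/27/24 (0.91) by the most. Of the 4 references, 3 (miR-103, miR-191 and miR-423-3p) lie in plate rows B, D, F and so on. The reference scales are not corrected for plate rows, whose difference of -1.47 in median log2 ratio is larger in size than those 3 medians. The scale of the authors' deposited values is not corrected for them either. Its offset of 0.7 cycles equals the difference of the well taken as UniSp6, which lies in row B. None of the 10 list medians lay outside the central 95% of random lists matched on level.

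Of 38 assays for markers of other cell types, 26 (68.4%) were at or above 35 cycles in both pull-downs, among them all 7 muscle miRNAs, against 63.0% of all miRNA assays. Such assays have no well assigned here, and 126 of the 238 wells at or above 35 cycles on both plates still gave a Ct on at least 1, so a low level in them is not excluded. 4 were measured in both, miR-9 at 7.22-fold, miR-126-3p, an endothelial miRNA, at 5.25-fold, miR-451 at 1.0-fold and miR-200c, an epithelial miRNA, at 0.815-fold. 7 were measured only with the control probe, including miR-122 of liver and miR-375, at Ct values of 34.62 and 34.72, and 1, miR-294, only with the Stat3 probe. None of the 48 assays for the imprinted Dlk1-Dio3 cluster, rat-named ones included, was below 35 cycles in either pull-down, nor were 14 of the 15 for the Sfmbt2 cluster. The exception, miR-297a, had a Ct of 34.98 with the control probe.

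The control wells did not share one ratio. The 3 UniSp3 calibrator wells differed between plates by 0.02, -0.76 and -1.91 cycles (control minus Stat3), with a mean of -0.89 ± 0.97 (SD, n = 3 wells) and a range of 3.82-fold. Their Ct varied by an SD of 0.29 on the control plate and 1.16 on the Stat3 plate, so a 2-fold difference in a single assay lies within the spread of these wells. Relative to the median of all miRNAs, 7 assays lay above and 11 below by more than the calibrator range of 1.93 cycles. That median pools all plate rows. Of those below, rno-miR-214, miR-582-3p, miR-345-3p, miR-101b, miR-582-5p and miR-449c lie in rows B, D, F and so on. The median log2 ratio of those rows was 0.85, so their distance includes the row difference given below. Of those above, miR-423-3p and miR-501-3p lie in the same rows. Of the small nuclear RNAs, U6 was at 4.33-fold, RNU1A1 at 0.699-fold and RNU5G at 0.472-fold, in plate rows J, N and L. U6 was near the 4.22-fold median of all miRNAs but above the 1.80-fold median of its own set of alternate rows, and the other 2 were below both. Ratios differed between alternate plate rows: 74 assays in rows A, C, E and so on had a median of 5.01-fold, with 61 at least 2-fold higher, and 26 assays in rows B, D, F and so on had a median of 1.80-fold, with 12 at least 2-fold higher.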

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

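All tests in this part were chosen after the results were seen. Wells outside the comparison gave a signal more often with the Stat3 probe. Of the 238 wells at or above 35 cycles in both pull-downs, which the comparison does not use and to which no assay name could be attached, 89 still gave a Ct with the Stat3 probe and 67 with the control probe. A Ct was given only with the Stat3 probe in 59 of them, only with the control probe in 37 and with both in 30, where the median log2 ratio was 1.52.

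The first pattern is the higher level of most miRNAs with the Stat3 probe. Raw Ct values with no offset gave a median log2 ratio of 1.38, but that follows by subtraction of the same 0.7 cycles from every assay, so it does not test which scale is right. One common factor for every small RNA, such as a larger yield, cannot be told apart from a change of miRNAs alone: the median of U6, RNU1A1 and RNU5G minus that of all miRNAs was -2.59 on the log2 scale, but against the miRNAs of their own plate rows the difference was -1.37, within 2 calibrator SD. A greater association of miRNAs with the Stat3 probe, the difference the design names, stays open and untested with 1 pull-down per probe.

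The second pattern is the lower ratio in plate rows B, D, F and so on, a difference of -1.47 in median log2 ratio from the other rows. Lower levels of the assays there do not account for it, since the median of those rows stood at percentile 0.13 of random lists matched on mean level, whose own median was 1.56, and at 0.01 and 0.62 when matched on the control or the Stat3 Ct alone. A loading difference common to alternate rows cannot be told apart from a difference between the assays placed there. The calibrator well in row B lay -1.54 from the mean of those in rows C and E, as such a difference would give. Yet the rat-named assays of miR-146b, miR-223 and miR-200c in rows N, D and F lay above the same-named mouse assays in rows O and M, by 0.21, 0.34 and 0.88 (median 0.34), and the other direction would be needed. These pairs are a weak check. The control Ct of miR-146b was 32.10 in the mouse assay and 28.29 in the rat-named one, and that of miR-200c was near the limit, at 33.71 and 34.33.

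The third pattern is the group of very large ratios. Low template stays open: the SD of the log2 ratio in the assays of lower level was 0.87 times that in the others, but the 39 assays past 35 cycles on 1 plate are left out of it and the level itself includes the Stat3 Ct, so the comparison decides nothing. Noise between wells stays open too: the SD over all 100 assays was 1.55, above the calibrator SD of 0.97. The 95% interval of the calibrator SD, 0.51 to 6.11 from 3 wells, is too wide for this comparison to exclude noise. That SD also includes the row B well, which lay -1.54 from the mean of the others, so it may hold a row difference. Of the assays, 18% lay over 2 calibrator SD from the median. Repeat plates of the same pull-downs would be needed to separate miR-25, miR-374 and miR-15b from such noise.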

How the results depend on the processing

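No paired analysis was possible because each probe has 1 pull-down and no test was run, and for the same reason no replicate could be left out. The 3 alternatives for seed matches in Stat3 mRNA were not run. Scaling to UniSp3, to the small nuclear RNAs, to raw Ct or to the reference miRNAs for the median and the lists, leaving miR-423-3p out of the references, centring within plate rows, other Ct limits, plate rows, wells with an instrument warning, rat-named assays and 1 assay per miRNA were chosen after seeing the data. Medians are listed where they moved by more than the calibrator SD of 0.97, which covers wells only, or changed sign, counts where they moved by over 1.5 times, and single miRNAs where a ratio of at least 2-fold changed sign. The number at least 2-fold higher, 73, became 16 centred on the median, 19 centred on the mean, 11 scaled to the reference miRNAs and 32 without miR-423-3p among them. It was 43 among 50 assays of higher level and 48 among 64 below a Ct of 33, where fewer assays enter, and 12 among 26 in rows B, D, F, a lower share than the 61 among 74 of the other rows. The number lower, 2, became 30, 25, 42 and 14 on the same 4 scales, 5 with any determined Ct, and 1 at higher level, at 4-fold, in rows A, C, E and in rows B, D, F. The median log2 ratio, 2.08, became -0.49 on the reference scale, 0.52 without miR-423-3p, which alone decides that sign, and 0.85 in rows B, D, F. It stayed between 1.38 and 2.33 under the other 6 alternatives. Among assays of higher level, r was 0.43 and rho 0.46, over a range of Ct that the selection narrows. With any determined Ct, 3 assays tied to a well were seen with the Stat3 probe only, and 59 wells without a name came on top. Centring on the median subtracts 2.08 from each log2 ratio, which by construction gave list medians of -0.40 (miR-17 seed), -0.46 (miR-17 cluster), 0.48 (let-7), -0.64 (miR-15/16), -0.98 (miR-29), 0.45 (miR-30), 0.38 (miR-23/27/24), -0.28 (macrophage), -0.59 (inflammation) and -0.58 (reported for Stat3). In the same order, the reference scale gave -0.90, -0.95, -0.017, -1.14, -1.48, -0.044, -0.11, -0.78, -1.08 and -1.07. Without miR-423-3p these were 0.12, 0.068, 1.002, -0.12, -0.46, 0.98, 0.91, 0.24, -0.064 and -0.053. Neither reference scale is corrected for plate rows. With each assay centred on the median of its own set of plate rows they were -0.15, -0.48, 0.23, -0.47, -1.23, 0.20, 0.13, -0.18, -0.76 and -0.48. All 10 list percentiles stayed on their side of the limits with unmatched random lists. Of 57 named miRNAs, 30 turned from higher to lower when centred, 11 of them under 2-fold before. The other 19 were at least 2-fold higher before: miR-484 -1.04, miR-222 -0.90, rno-miR-146b -0.88, miR-142-3p -0.79, miR-151-5p -0.71, miR-20a -0.23, miR-21 -0.51, miR-16 -0.00037, miR-17 -0.58, miR-106a -1.05, miR-19b -0.46, miR-195 -0.82, miR-322 -0.46, miR-29a -0.20, miR-29c -0.98, miR-30c -0.53, miR-130b -1.05, miR-191 -0.055 and miR-146a -0.59. Single miRNAs were not centred within plate rows. Of the 19, miR-191 (log2 ratio 2.02), miR-322 (1.61), miR-151-5p (1.37), rno-miR-146b (1.20) and miR-106a (1.03) lie in rows B, D, F and so on. They were above the median of those rows, 0.85, so for them the turn depends on the pooled median. The rest lie in rows A, C, E and so on and were below the median there, 2.33. Keeping the first of repeated assay names removed no miRNA assay, so it tested nothing. With 1 assay per miRNA, dropping the rat-named assays of miR-146b, miR-223 and miR-200c, 72 of 97 were at least 2-fold higher and 2 lower. Wells near 35 cycles hold little template, and no depth is known for them.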

Other observations

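Several miRNAs outside the fixed lists were also higher with the Stat3 probe, here named after their values were seen. miR-501-3p was 24.7-fold higher, from a Ct of 34.97 with the control probe, just under the limit, and its genomic neighbour miR-532-5p had a ratio of 0.146, the widest gap among the 29 neighbour pairs below. miR-324-3p was at 12.3-fold and miR-324-5p, from the other arm of the same precursor, at 4.42-fold, while miR-151-3p was at least 116-fold higher and miR-151-5p only 2.58-fold. The erythroid miRNA miR-144 was measured only with the control probe, at a Ct of 34.37, and miR-451, from the same cluster, was at 1.0-fold. The well of miR-144 carried an instrument warning in either pull-down or both.

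It was asked, after the ratios had been seen, whether miRNAs of one genomic cluster or of one seed family had like ratios. Genes were found in the mouse gene table for 83 of the 94 mouse-named assays measured in both pull-downs, and 29 pairs of 38 assays had genes within 10 kb. Their median absolute log2 difference was 0.83, against 1.25 for random sets matched on level, at percentile 5.74. For 56 pairs within 6 seed families, 28 of them within let-7, it was 0.87 against 1.31, at percentile 6.11. Since 24 of the neighbour pairs and 44 of the family pairs lie within 1 set of alternate plate rows, the random sets were also matched on those rows, which gave percentiles of 4.49 and 7.04 with level matched and 5.53 and 5.66 without. All 6 percentiles lie below the random median and miss the limit of 2.5 set for them, so neither shared transcription nor a shared seed is shown to set the ratios, and neither is excluded. The 6 reuse the same 29 and 56 pairs, and some pairs, such as miR-15b and miR-16, are in both sets. They are therefore not separate evidence. Signal shared between like assays, raised above for let-7, was not tested. Of the pairs, miR-99b and miR-125a-5p differed by 0.59, miR-23b and miR-24 by 0.04, miR-25 and miR-93 by 3.72, and let-7a and let-7f by 2.59.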
